A study of Homo sapiens with 16 samples.

How the data were processed

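The study measured DNA methylation by capture of methylated DNA and sequencing (MBD-seq) in H7 human embryonic stem cells and in 3 stages derived from them. Cells at passage 60 were plated with 10 µM of the ROCK inhibitor Y-27632, treated with 12 µM of the WNT activator CHIR99021 for 24 hours and then with 5 µM of the WNT inhibitor IWP4 for 2 days. Primitive mesoderm (day 3) and cardiac mesoderm (day 4) were isolated by cell sorting on ROR2 and on ROR2 with PDGFRA, and cardiomyocytes (day 31) by Percoll gradient. From 3.5 µg of sonicated DNA, size selected at 100 to 300 bp, methylated fragments were captured with the MethylMiner kit in a single elution. Input libraries came from 1% of the same DNA. Libraries had 13 cycles of PCR and were read in paired mode at 100 cycles per end. Each stage had 2 MBD and 2 input libraries.

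The authors aligned reads to hg19 with Bowtie (version not given) and annotated regions with HOMER 4.7 and GENCODE 18. The caller, its threshold and its use of the input were not given, and the score column of the 12 files was 0 throughout. The deposited values are a signal, the authors' mean normalised read density over a window of fixed width per file at each region, in 16 libraries. That window was 99 bp wide in 8 files, and 199 bp in the higher lists of PMESO to CMESO and hESC to CMESO. It was 299 bp in the lower list of CMESO to cardiomyocytes and 399 bp in the lower list of PMESO to cardiomyocytes. In the lists with wider windows 71.1% to 91.5% of regions were only 99 bp wide. The signal given for these regions therefore also covers flanking sequence. Signal is not compared between lists of different window width, except that the closing part on the cardiomyocyte input pools regions of several lists. The scale factor of the signal is unknown. The values are not counts, so edgeR and DESeq2, which the plan allowed for counts, were not used. Depth was read from the step of 1 fragment. At single-window regions of the 99 bp files, at least 99.99% of the values of each library were whole multiples of it within 0.05. The step limits precision and covers counting error only. Of the 47059 regions 80.0% were a single 99 bp window. The direction of the signal was that of the file name in all but 1 region.

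A region was assigned to the gene the file named and to the gene of the RefSeq transcript in its detailed annotation, 12300 of 12630 such identifiers being matched to a symbol. In this way 37.7% of regions had a gene (15.3% of Alu and 48.0% of other regions), 8504 genes in all, which formed the background of every gene test. Regions without a gene entered no gene test. Each gene list was cut to its members in this background, so its totals and shares leave out members without any region. Annotation classes and repeat classes were read from the files, with CpG island, Alu, L1, LTR and other classes from the detailed annotation. Where a gene had several regions in a list, the values given are those of the region with the largest difference of means, unless stated otherwise.

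The comparisons, gene lists, tests and the rule for named genes were set before the data were examined, and the repeat classes and the limma fit were added after that. The rule named, per comparison, up to 4 members with most regions of each gene list described, the 5 genes with most regions in each direction (ties by symbol) and 20 core genes. Its part on the authors' scores was not applicable, since all scores were 0. The higher share of regions has an exact binomial (Clopper-Pearson) 95% interval. Annotation and repeat classes of higher and lower regions were compared by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 42 tests each and a threshold of 0.05. Chromosomes with at least 20 regions per list served as units in a permutation test with 100000 draws, whose smallest p is 1e-05. Each of 21 gene lists was tested for the number of genes with a region against the other background genes (252 tests), and for direction against the other regions (126 tests), by the same test. Regions, genes and chromosomes are not replicates, since all come from the same libraries, so these tests compare lists, not cultures.

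Overlap of at least 1 bp was computed with bedtools 2.31.1. For lists that share libraries, the overlap without any difference between stages was simulated with 1000000 and 10000000 windows and a dispersion between replicates of 0.00496. For each list, limma 3.58.1 in R 4.3.3 was fitted to the log2 of signal + 0.5 in the 8 MBD libraries with a trended variance, and the contrast was that of the 2 stages not compared by the list. Replicate numbers did not pair the stages (correlation of replicate differences across regions from −0.046 to 0.0030), so no block was used. Other calculations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures matplotlib 3.10.9. The tests were checked on simulated data, with 11 of 11 checks passed.

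Alternatives covered the length covered by regions, merging within 1000 bp, leaving out Alu regions, the larger signal differences, chromosomes as units, regions within 10000 bp of a start site, leaving out intergenic regions, gene lists drawn at random with matched numbers of regions (10000 and 100000), other overlap rules, pseudocounts of 0.1 and 1, a minimum mean signal of 1, a replicate block, a fit to 4 libraries and leaving out each replicate. Other splits of the samples were not counted, since each group had 2 libraries. A reference genome was not used here, so CpG density was not computed. Results for some single genes are not reported here.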

Results

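DNA methylation was profiled at 4 stages as H7 human embryonic stem cells (hESC) were turned into cardiomyocytes. The stages were undifferentiated hESC, primitive mesoderm (PMESO, day 3, sorted on the WNT receptor ROR2), cardiac mesoderm (CMESO, day 4, sorted on ROR2 and PDGFRA) and cardiomyocytes (day 31, enriched on a Percoll density gradient). Methylated DNA was captured with a methyl-CpG binding domain (MBD) protein and sequenced, with 2 MBD libraries and 2 input libraries per stage, 16 libraries in all. The data are 12 lists of regions that the authors called as higher or lower in the later stage of each of the 6 stage pairs, together 47059 regions at 44341 unique coordinates (hg19). Each region carries the authors' normalised read density in all 16 libraries, called signal here. Values of a region are the mean ± SD of the 2 MBD libraries of a stage (n = 2), first the earlier stage and then the later one. No fold is given where the lower mean stood on a count of 3 or fewer over both libraries. That count adds up fragments over each 99 bp of the window. In lists with wider windows the same fragment can be counted repeatedly. The lower mean of a fold there can therefore stand on 3 fragments or fewer. The largest folds given, at CACNA1D, VWF, RYR2 and TNNT2, come from such lists and are uncertain for that reason. "Higher" and "lower" always refer to the later stage and to captured DNA, not to gene expression.

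Total read counts were not given, and depth was read from the smallest step between signal values, which corresponds to 1 fragment. That step was 0.296 and 0.272 in the hESC MBD libraries and 0.210 and 0.241 in PMESO. It was 0.413 and 0.259 in CMESO and 0.239 and 0.289 in cardiomyocytes. CMESO replicate 1 was therefore the shallowest MBD library, by 1.97 times against the deepest. At single-window regions of the 99 bp files, 28.9% of its values were 0, against 4.10% to 11.8% in the other MBD libraries. These files hold the lists selected as low in CMESO and none selected as high in it. The share of zeros in CMESO therefore reflects selection as well as depth. Input steps ran from 0.133 to 0.234. Across 27860 regions, MBD replicates of a stage correlated at a Spearman coefficient of 0.638 in CMESO to 0.776 in PMESO, while input replicates correlated at 0.117 to 0.129, and at 0.383 in cardiomyocytes. These correlations are across regions, which are not independent replicates. The regions were selected on MBD signal, and in nearly all of them both MBD replicates of the compared stages lay apart. Part of the MBD correlation comes from that selection, so its contrast with the input does not measure replicate quality. With 2 libraries against 2, an exact permutation test cannot give a p below 0.333. No region was retested between the stages its own list compares, since differences between those stages carry the authors' selection.

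**Figure D1:**
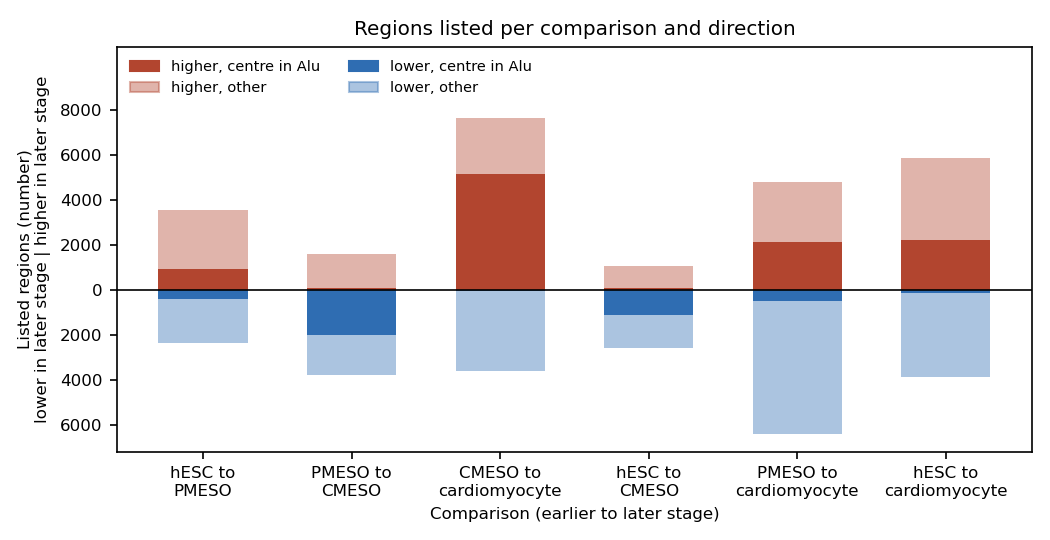
Number of regions (y axis) that the authors called higher or lower in the later stage of each of the 6 comparisons (x axis), with the part of each bar that lies at Alu elements drawn dark. Alu elements made up 5144 of the 7639 regions higher in cardiomyocytes than in CMESO, and 55 of the 3597 lower ones.

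The step from hESC to PMESO asks which methylated regions change as pluripotent cells enter the mesoderm. More regions were higher in PMESO than lower, 3530 against 2354, or 60% (exact 95% interval of counting error, 58.7% to 61.2%). TBX3, a T-box factor of early heart and limb development, had a higher exon region at chr12:115112002–115112700, with a signal of 0.580 ± 0.43 to 1.88 ± 0.62, 3.24-fold. The promoter of the imprinted RNA gene H19 at chr11:2019602–2019700 was also higher, 0.556 ± 0.37 to 3.14 ± 0.019, 5.64-fold. So was a region assigned to TMEM88, a WNT inhibitor of the cardiac mesoderm named after its values were seen (chr17:7756502–7757300, 0.556 ± 0.37 to 3.18 ± 0.78, 5.71-fold). ROR2, the receptor used for the sort, carried an intron region that was higher (chr9:94600802–94601000, 1.54 ± 0.71 to 5.22 ± 0.10, 3.39-fold) and another that was lower (chr9:94697202–94697300, 2.10 ± 0.88 to 0.120 ± 0.17). CACNA1C, the pore of the cardiac L-type calcium channel, had 4 lower regions, led by chr12:2281802–2281900 in an intron with 3.27 ± 0.39 to 0.572 ± 0.21, 5.73-fold, and 1 higher region in an exon.

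Among the genes with most regions, the histone demethylase KDM4B and PRDM16, a transcriptional regulator of heart and brown fat, had 5 higher regions each. CASZ1, a zinc finger factor needed in the heart, the fibrillar collagen gene COL5A1 and the mitotic checkpoint gene MAD1L1 had 4 each. Their strongest differences were KDM4B (2.12 ± 0.078 to 5.80 ± 0.72), PRDM16 (1.11 ± 0.74 to 4.45 ± 0.85), CASZ1 (0.586 ± 0.64 to 3.52 ± 0.22), COL5A1 (1.14 ± 0.065 to 4.78 ± 0.97) and MAD1L1 (2.58 ± 0.95 to 7.69 ± 1.4). Lower regions were most frequent at CACNA1C and the cadherin gene CDH4, with 4 each, and at genes such as CACNA1C-AS4 and CASC15, with 3 each. Here and in the later comparisons, counts of regions per gene were not set against gene length or CpG content. A long gene can hold more regions for that reason alone. CDH4 had 3.57 ± 0.81 and 0.781 ± 0.084 in the region at chr20:60298102–60298200.

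Totals of gene lists count only members with a region in at least 1 of the 12 lists. Of the 22 such pluripotency genes, 5 had a higher region and 0 a lower one. They included USP44, the de novo methyltransferase gene DNMT3B, the RNA-binding LIN28B and PRDM14. DNMT3B was higher at its transcription end (chr20:31397402–31397500, 2.41 ± 0.062 to 6.88 ± 3.2, 2.86-fold), and LIN28B in an intron (chr6:105433902–105434000, 0.148 ± 0.21 to 2.10 ± 0.59). Counted as regions this was 6 against 0, with an adjusted p of 0.585 for direction by Fisher's exact test, two-sided. In the sarcomere list 6 of 34 genes had a higher region, among them TTN (2.48 ± 0.16 to 6.47 ± 0.81), ACTN2 (0.841 ± 0.35 to 3.67 ± 1.6), LDB3 (1.52 ± 1.3 to 4.84 ± 0.30) and MYL3 (1.00 ± 0.26 to 3.73 ± 0.51), and 2 had a lower one (adjusted p = 1 each). Calcium and ion channel genes had a higher region at 9 of 34 (adjusted p = 0.606), among them CACNA1D (chr3:53779702–53779800, an exon, 1.43 ± 0.48 to 4.72 ± 0.13) and ABCC9 (chr12:21951702–21951800, a 3' UTR, 0.148 ± 0.21 to 2.04 ± 0.51). Among 17 cardiac mesoderm genes, 5 were at higher and 2 at lower regions (adjusted p = 0.747 and 1), and the VEGF receptor gene KDR had a higher region (0.136 ± 0.19 to 1.92 ± 0.34) and a lower one (3.74 ± 0.69 to 0.857 ± 0.32, 4.36-fold). Germline genes were at higher regions for 4 of 12 (adjusted p = 0.747), such as TEX101 (chr19:43906002–43906100, an intron, 0.136 ± 0.19 to 1.74 ± 1.1), and a HORMAD2 intron was listed at 0 in hESC and at 1.46 ± 0.021 in PMESO. Imprinted genes were split evenly, with 4 regions higher and 4 lower among 29 genes, and the endoderm list of 8 genes had no region in either list.

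CpG islands held 139 higher regions and 1 lower one (adjusted p = 1.4e-29, Fisher's exact test, two-sided, over 42 repeat and island classes). Exons held 6.40% of higher and 2.93% of lower regions (adjusted p = 3.3e-09), and introns 45.0% against 50.1% (adjusted p = 4.1e-04). Alu elements, short repeats rich in CpG, made up 26.8% of higher and 17.0% of lower regions (adjusted p = 2.3e-18). Across the list of higher regions the median signal was 0.70 ± 0.16 in hESC and 3.37 ± 0.0021 in PMESO. It was 2.76 ± 0.14 and 0.33 ± 0.13 in the list of lower regions. Input medians at these regions were near 1 in hESC and PMESO. Among the regions above the median signal difference of this comparison, 50.2% were higher.

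The step from PMESO to CMESO, a day apart in culture, asks what differs between the ROR2-sorted and the ROR2 and PDGFRA-sorted mesoderm. Most called regions were lower in CMESO, 3776 against 1604 higher (29.8% higher, 28.6% to 31.1%). ROR2 itself had 4 lower regions and no higher one, led by an intron region at chr9:94575802–94575900 with 4.18 ± 1.8 to 0.725 ± 0.44, 5.76-fold. A lower region upstream of GATA4, a founding factor of the heart programme, lay in an Alu element at chr8:11497702–11497800, 2.33 ± 0.57 to 0.206 ± 0.29. The intron of the WNT ligand gene WNT3 at chr17:44860002–44860100 was 1.91 ± 0.023 in PMESO and listed at 0 in CMESO. In the other direction, an exon of ALDH1A2, which makes retinoic acid, was higher (chr15:58256202–58256300, 0.735 ± 0.45 to 2.70 ± 0.30, 3.68-fold), as was the promoter of the muscle filament gene DES (chr2:220282302–220282400, 0.423 ± 0.081 to 2.49 ± 1.6, 5.88-fold).

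Genes with most lower regions after ROR2 were PNMA8B, the phosphatase subunit gene PPP2R5C and SORBS2, an adaptor of the cardiac Z-disc, with 3 each, and ABL1 with 2. Their leading regions were PNMA8B (chr19:46997602–46997700, an exon, 6.48 ± 1.7 to 2.18 ± 1.3), PPP2R5C (chr14:102385902–102386100, an intron, 2.95 ± 0.43 to 0.195 ± 0.28) and SORBS2 (chr4:186697902–186698000, a promoter, 4.48 ± 0.21 to 1.06 ± 0.33). Higher regions were most frequent at KAZN with 4, at the amino acid transporter gene SLC7A1 and the netrin receptor gene UNC5D with 3, and at ADAMTS2 and ADARB2 with 2. They included KAZN (chr1:15303902–15304100, an intron, 0.398 ± 0.12 to 3.18 ± 0.47), SLC7A1 (chr13:30277102–30277200, intergenic, 0.845 ± 0.078 to 3.71 ± 1.0) and UNC5D (chr8:35352202–35352600, an intron, 0.496 ± 0.19 to 2.73 ± 1.1).

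In the WNT list 8 of 38 genes had a lower region and 3 a higher one (adjusted p = 0.781 and 1). Besides ROR2 the genes with a lower region included AXIN1, a scaffold of the beta-catenin destruction complex, with 5.44 ± 1.2 and 1.47 ± 0.25, the receptor gene FZD8 (chr10:35943402–35943500, intergenic, Alu, 2.49 ± 0.55 to 0.259 ± 0.37) and the co-receptor gene LRP5, which was at 1.58 ± 0.15 in PMESO and listed at 0 in CMESO. Primitive streak genes had 5 lower regions and 0 higher, 4 of them at ROR2 (adjusted p for direction = 0.823). The DNA methylation list had lower regions at 4 of 14 genes and higher regions at none (adjusted p = 0.76 and 1). Its members were DNMT3A (chr2:25569102–25569200, intergenic, Alu, 5.48 ± 0.27 to 1.09 ± 0.80), ZBTB38 (5.95 ± 0.089 to 1.71 ± 1.2), MBD5 (3.56 ± 0.61 to 0.648 ± 0.92) and UHRF2 (2.07 ± 1.2 to 0.130 ± 0.18). Epithelial genes were at lower regions for 2 of 13, CDH1 or E-cadherin (5.14 ± 0.46 and 1.30 ± 1.8, Alu) and EPCAM (2.66 ± 0.70 and 0.259 ± 0.37, Alu), with an adjusted p of 1. Pluripotency genes had 4 lower regions and 0 higher (adjusted p = 0.964), at DPPA2, ESRRB, VRTN and ZSCAN10. The sarcomere list had 3 higher and 2 lower regions (adjusted p = 0.978), with TPM1 (0.990 ± 0.21 to 3.48 ± 0.39) and FHOD3 (0.899 ± 0.086 to 3.21 ± 0.88) higher. Smooth muscle and fibroblast genes had 3 lower regions and 0 higher, such as COL1A1 (3.35 ± 0.32 to 0.259 ± 0.37) and FBN1 (2.34 ± 0.25 to 0.259 ± 0.37), and endothelial and blood genes 3 higher and 4 lower (adjusted p = 1 each).

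Alu elements were 52.9% of lower and 5.86% of higher regions (1996 and 94, adjusted p = 1.1e-272, Fisher's exact test, two-sided). Without Alu regions 45.9% of regions were higher. Intergenic sequence held 43.0% of higher and 33.6% of lower regions (adjusted p = 4.3e-10), introns 46.7% against 53.8% (adjusted p = 5.9e-06) and promoters 2.37% against 4.16% (adjusted p = 0.0029). Median signal in the lower list was 3.04 ± 0.13 in PMESO and 0.259 ± 0.37 in CMESO, where CMESO replicate 1, the shallowest library, had a median of 0. In the higher list it was 0.333 ± 0.047 and 2.25 ± 0.33. Input medians were near 1 in both stages.

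The step from CMESO to cardiomyocytes asks how methylation differs between cardiac mesoderm and day 31 cardiomyocytes. Genes of the sarcomere, the contractile unit of muscle, stood out among regions lower in cardiomyocytes. Among genes with a region in any list, a lower region was found at 16 of 34 sarcomere genes (47.1%), against 17.6% of the others (adjusted p = 0.0089, Fisher's exact test, two-sided, over 252 tests). MYH6, the atrial myosin heavy chain, had 4 such regions, led by an exon region at chr14:23874402–23874600 with 3.98 ± 2.0 to 0.791 ± 0.11, 5.03-fold. An intron of TNNT2, cardiac troponin T, was lower at chr1:201343802–201344000 (2.12 ± 0.37 to 0.223 ± 0.093, 9.51-fold), as were regions next to MYH7, the ventricular myosin heavy chain (chr14:23907602–23907900, 2.40 ± 1.3 to 0.344 ± 0.077, 6.98-fold), and in an exon of TTN (chr2:179412302–179412400, 3.63 ± 1.1 to 1.05 ± 0.018, 3.47-fold). Cardiac transcription factor genes were frequent among the higher regions, at 12 of 20 genes against 1700 of 8484 others (adjusted p = 0.0089, and 0.0283 to 0.567 over its alternatives), but their regions were 15 higher and 17 lower (adjusted p for direction = 1).

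Further sarcomere genes with a lower region included NEBL, ACTN2, FHOD3, LDB3, LMOD3, MYH7B, MYL3, SVIL, TNNI1, TPM1 and TRIM63, all but NEBL named after their values were seen. NEBL, a Z-disc protein, had 2.13 ± 0.69 and 0.273 ± 0.16 at chr10:21158602–21158700. LDB3, which anchors alpha-actinin, had 2.73 ± 0.54 and 0.419 ± 0.37 at chr10:88428202–88428600, and MYL3, a myosin light chain, had 2.00 ± 0.10 and 0.128 ± 0.045 at chr3:46903302–46903400. Higher regions were found at 7 of the 34 genes (adjusted p = 1), such as TTN in another exon (chr2:179574402–179574500, 0.389 ± 0.55 to 2.95 ± 0.90) and SMYD2. Sarcomere genes had 9 higher and 19 lower regions (adjusted p for direction = 0.658). Without regions between genes the excess of sarcomere genes no longer passed the threshold (adjusted p = 0.213, and from 0.0121 over all alternatives).

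The 12 cardiac transcription factor genes with a higher region were PRDM16, CASZ1, IRX3, MEF2A, TEAD1, ZFPM2, GATA4, IRX2, IRX5, SRF, TBX2 and TBX5, of which TEAD1, ZFPM2, IRX2, IRX5, SRF and TBX2 were named after their values were seen. IRX3, a homeobox factor of the ventricular conduction system, had 3 higher regions, and the one at chr16:54325802–54326000 was listed at 0 in CMESO and at 2.39 ± 0.51 in cardiomyocytes. TBX5, mutated in Holt-Oram syndrome, was listed at 0 in CMESO and at 1.75 ± 0.79 in cardiomyocytes in an intron at chr12:114831302–114831400. GATA4 had a higher region at chr8:11516602–11516700 (0.259 ± 0.37 to 2.52 ± 1.5) and a lower one at chr8:11518702–11518800 (3.41 ± 1.0 to 0.903 ± 0.19, 3.77-fold), both intergenic. PRDM16 had 1 higher and 5 lower regions, the latter led by chr1:3115402–3115700 (5.21 ± 0.94 to 1.17 ± 0.15, 4.46-fold). Lower regions were found at 8 of the 20 genes (adjusted p = 0.511). With regions within 10000 bp of a start site alone, or without intergenic regions, the excess of higher regions at these genes was no longer past the threshold (adjusted p = 0.567 and 0.545).

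Among pluripotency genes 9 of 22 had a higher region and 2 a lower one (adjusted p = 0.548 and 1). The NANOG promoter at chr12:7941602–7941700 was listed at 0 in CMESO and at 2.62 ± 0.016 in cardiomyocytes. SOX2 was higher in an Alu element at chr3:181463702–181463800 (1.53 ± 0.41 to 5.81 ± 0.79, 3.80-fold), the NODAL co-receptor gene CRIPTO at its promoter (chr3:46618202–46618300, 0.206 ± 0.29 to 2.78 ± 1.5), and DNMT3L upstream of the gene (0.259 ± 0.37 and 2.59 ± 0.39). BMP, NODAL and TGF-beta genes had 6 higher and 9 lower regions (adjusted p for direction = 1). The inhibitors SMAD7 and SMAD6 carried 4 and 2 of the lower ones, led by the SMAD7 promoter at chr18:46460502–46460600 (3.09 ± 0.70 to 0.704 ± 0.094, 4.39-fold) and by SMAD6 (chr15:67056602–67056800, an intron, 4.00 ± 0.58 to 1.02 ± 0.078), and BAMBI (chr10:28971002–28971300, an exon, 3.36 ± 0.27 to 0.454 ± 0.37) was lower as well. RYR2, the calcium release channel of the sarcoplasmic reticulum, had 2 lower regions, led by chr1:237547602–237547700 (2.53 ± 1.9 to 0.232 ± 0.22, 10.9-fold), and calcium and ion channel genes were at lower regions for 10 of 34 (adjusted p = 0.76). Zinc finger genes had 42 higher and 19 lower regions (adjusted p = 0.412). The endoderm list had lower regions at FGB, FGG and PROX1, 3 of 8 genes, and a higher one at CER1, while the neural list had 5 lower regions and 1 higher (adjusted p = 0.986 and 0.751 for direction). Skeletal muscle genes had 5 higher and 2 lower regions (adjusted p = 1), among them MYH2 (0 in both libraries to 1.73 ± 0.42), MYBPC1 (1.20 ± 0.052 to 5.50 ± 1.0) and KLHL41 (4.04 ± 0.33 to 1.16 ± 0.95).

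By number of regions, LOC100507511 and TIAM1, an activator of the GTPase RAC, led the higher list with 5 each, before DMD, FA2H and LOC100506641 with 4. CAMTA1 and the glycosyltransferase gene GALNT2 led the lower list with 6, before PRDM16 and RPTOR with 5 and COL4A2 with 4. Examples were TIAM1 (chr21:32889102–32889200, an intron, Alu, 0.725 ± 0.44 to 3.89 ± 0.58) and GALNT2 (chr1:230313002–230313300, an intron, 4.93 ± 0.62 to 1.13 ± 0.094). Regions were more often higher than lower, 7639 against 3597 (68.0%, 67.1% to 68.8%), and this turned over without Alu regions, with 41.3% higher. Alu elements were 67.3% of higher and 1.53% of lower regions, an odds ratio of 133, in the same direction on 23 of 23 chromosomes (adjusted p = 2.3e-05, permutation over chromosomes). All chromosomes come from the same libraries, so this p does not measure spread between cultures. CMESO replicate 1 was the shallowest library, and over lists that did not involve CMESO, Alu regions minus other regions were at −0.27 (log2) in CMESO replicate 1 and −0.17 in replicate 2. Exons held 1.71% of higher and 3.95% of lower regions (adjusted p = 5.4e-11), but without Alu regions this difference reversed, to 0.348 points more among the higher ones (adjusted p = 0.614). Intergenic sequence held 40.7% against 34.5% (adjusted p = 1.4e-09). Median signal was 0.259 ± 0.37 in CMESO and 3.26 ± 0.11 in cardiomyocytes in the higher list, and 2.48 ± 0.20 and 0.431 ± 0.065 in the lower list.

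**Figure D2:**
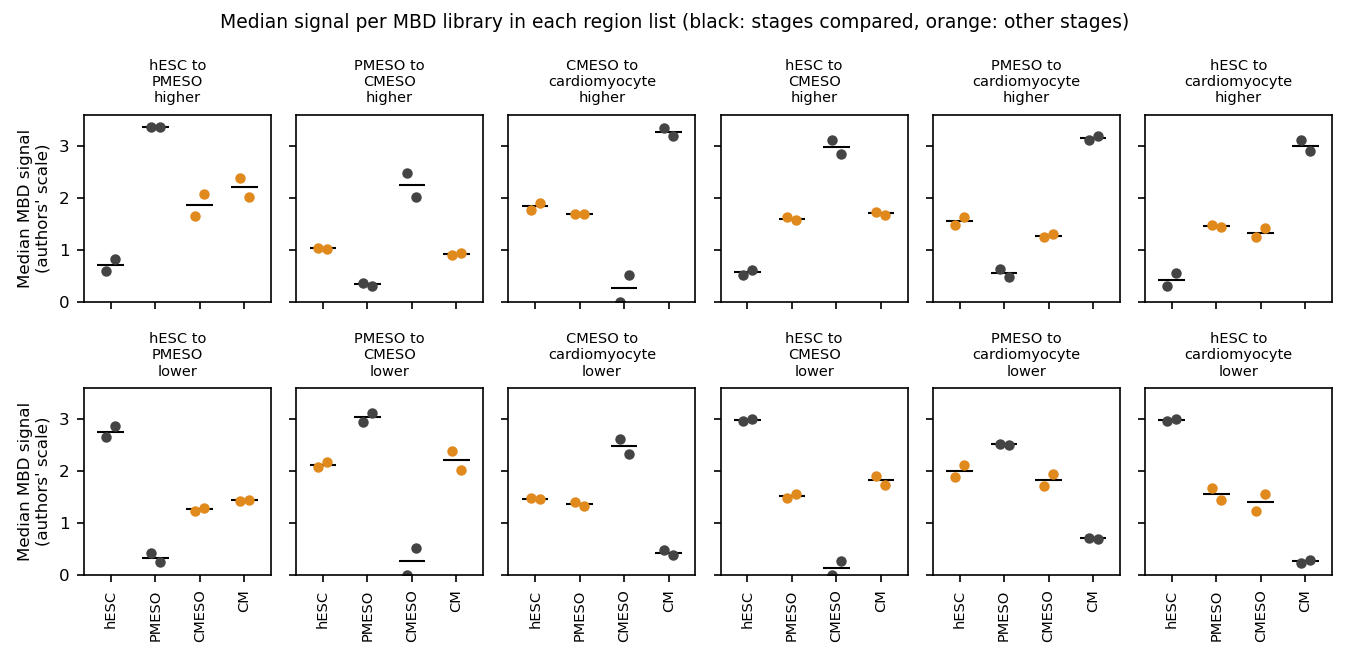
Median MBD signal (y axis, the authors' normalised read density) of each library (points, lines are means of 2 libraries) in each of the 12 lists, with the stages a list compares in black and the other stages in orange. Regions lower in CMESO than in PMESO had a median of 3.04 in PMESO and 0.259 in CMESO, and values between these in the other stages.

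From hESC to CMESO the comparison covers induction up to the sorted cardiac mesoderm. It held the fewest regions, 1067 higher and 2586 lower (29.2% higher, 27.7% to 30.7%). TBX3 was higher again in the exon at chr12:115112102–115112600 (0.509 ± 0.43 to 2.38 ± 1.3, 4.67-fold), and TBX2, a related repressor of chamber genes, in its 3' UTR (chr17:59485602–59485700, 0.253 ± 0.26 to 2.12 ± 0.66, 8.39-fold). The 5' UTR of HOXA7, a patterning factor, was higher at chr7:27196702–27196900 (0.426 ± 0.024 to 3.14 ± 0.23, 7.38-fold). DNMT3A and DNMT3B, which methylate DNA de novo, both had lower intergenic regions in Alu elements, at chr2:25569102–25569200 (5.49 ± 1.5 to 1.09 ± 0.80, 5.05-fold) and chr20:31342002–31342200 (3.66 ± 0.99 to 0.298 ± 0.13). An exon of TNNI3, cardiac troponin I, was lower at chr19:55665402–55665500 (5.36 ± 0.89 to 1.34 ± 0.44, 3.99-fold).

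Cardiac transcription factors had 3 higher and 3 lower regions (adjusted p for direction = 1), the lower ones including CASZ1 (chr1:10833102–10833200, an intron, 3.12 ± 0.18 to 0.206 ± 0.29) and MEF2D (chr1:156445102–156445200, an intron, 4.92 ± 1.5 to 0.984 ± 0.81). In the imprinted list 3 regions were higher and 4 lower (adjusted p = 1). The H19 promoter was higher (chr11:2019602–2019700, 0.874 ± 0.30 to 3.61 ± 0.29, 4.14-fold) and an Alu element near H19 was lower, and IGF2R, the receptor that clears IGF2, also had a higher region (0.580 ± 0.53 to 2.51 ± 0.76, 4.33-fold) and a lower one (2.82 ± 0.64 to 0.259 ± 0.37). Energy metabolism genes had 0 higher and 3 lower regions (adjusted p = 1), at the myoglobin gene MB (chr22:36011902–36012000, a promoter, 6.36 ± 0.64 to 1.68 ± 0.54), at PRKAG2 (2.53 ± 0.66 to 0.130 ± 0.18) and at PPARA, which was at 2.00 ± 0.52 in hESC and listed at 0 in CMESO. WNT genes had 4 higher and 7 lower regions (adjusted p = 1), with LRP5 (2.07 ± 0.93 to 6.21 ± 0.75), AXIN2 (1.72 ± 0.55 to 5.18 ± 1.8) and DVL2 (3.73 ± 1.6 to 0.466 ± 0.074) among them. BMP, NODAL and TGF-beta genes had 3 higher and 2 lower (adjusted p = 0.823), such as CHRD (1.32 ± 0.83 to 5.39 ± 0.85), BMP6 (0.937 ± 0.55 to 3.41 ± 0.87) and BMPR1A (5.20 ± 1.5 to 1.04 ± 1.5). The endothelial gene VWF had an exon region that was higher (chr12:6166002–6166300, 0.245 ± 0.037 to 3.11 ± 0.73, 12.7-fold) and an Alu region that was lower, within 2 higher and 3 lower regions of that list (adjusted p = 1). Germline genes were at 1 higher and 2 lower regions, and pluripotency genes at 1 of each. Neither the primitive streak nor the epithelial list had a region.

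Genes with most regions were KCNH5, a potassium channel, and the guidance cue NTN1 with 3 higher each, before CACNA2D3, FAM83B and HAVCR1P1 with 2. DSCAML1, the ephrin receptor gene EPHA7, GRID1, NAV2 and NTM had 3 lower regions each. They included NTN1 (chr17:9131802–9131900, an intron, 1.61 ± 0.44 to 5.54 ± 0.24), FAM83B (chr6:54801302–54801400, an intron, 0.0365 ± 0.052 to 2.44 ± 0.059), EPHA7 (chr6:94275602–94275700, intergenic, Alu, 5.05 ± 1.7 to 1.06 ± 0.33) and NAV2 (chr11:19920602–19920700, an intron, 3.28 ± 0.79 to 0.466 ± 0.074). CpG islands held 43 higher and 2 lower regions (adjusted p = 7.2e-21) and exons 6.37% against 2.40% (adjusted p = 7.7e-08). Introns held 44.3% of higher and 55.6% of lower regions (adjusted p = 3.3e-09), and promoters 4.59% against 2.55% (adjusted p = 0.0058). Alu elements were 8.62% of higher and 43.0% of lower regions (adjusted p = 2.6e-103, Fisher's exact test, two-sided), and 39.8% of regions were higher without them. The median signal was 0.564 ± 0.069 and 2.98 ± 0.18 in the higher list, and 2.98 ± 0.029 and 0.130 ± 0.18 in the lower one, in which CMESO replicate 1 again had a median of 0. Input medians lay near 1.

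From PMESO to cardiomyocytes the question is what changes over the whole course after the first mesoderm stage. Regions were more often lower, 6392 against 4794 (42.9% higher, 41.9% to 43.8%). SMAD7, an inhibitor of BMP and TGF-beta signals, had 8 lower regions and no higher one, led by chr18:46467102–46467300 in an intron with 3.92 ± 0.49 to 1.37 ± 0.60, 2.87-fold. PRDM16 had 9 lower regions and 1 higher, and the corepressor gene SKI had 5, led by chr1:2203602–2203900 (4.64 ± 0.61 to 1.10 ± 0.035, 4.23-fold). ROR2 had 6 lower regions, with 3.06 ± 0.83 and 0.212 ± 0.25 at chr9:94535502–94535800. In the other direction the exon of POU5F1, or OCT4, the central pluripotency factor, was higher at chr6:31138102–31138500 (0.331 ± 0.13 to 2.88 ± 1.0), and TBX3 had 3 higher regions, led by an exon region at chr12:115109702–115110100 (0.105 ± 0.15 to 3.65 ± 0.25).

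Calcium and ion channel genes had lower regions at 19 of 34 genes against 30.0% of the others (unadjusted p = 0.0021, adjusted p = 0.135). ATP2A2, the calcium pump of the sarcoplasmic reticulum, was lower in an intron (chr12:110776202–110776300, 2.56 ± 0.38 to 0.785 ± 0.24, 3.26-fold), CACNA1C at 3 regions (1 was higher) led by chr12:2516602–2516800 (4.90 ± 0.89 to 1.52 ± 0.21, 3.21-fold), and CACNA1D in an intron (chr3:53741102–53741300, 2.31 ± 0.14 to 0.119 ± 0.17, 19.3-fold). RYR2 had a higher intron region instead (chr1:237923102–237923300, 0.0600 ± 0.085 to 2.08 ± 0.27). Energy metabolism genes had lower regions at 9 of 15 (adjusted p = 0.511), among them mitochondrial creatine kinase CKMT2 (chr5:80528502–80528600, a promoter, 1.64 ± 0.57 to 0.281 ± 0.062) and the coenzyme Q gene COQ8A (4.26 ± 0.23 to 1.46 ± 0.17), while ESRRG, a nuclear receptor of oxidative metabolism, had 5 higher and 1 lower. The natriuretic peptide gene NPPA was lower in its 5' UTR (chr1:11908102–11908200, 1.82 ± 0.58 to 0.459 ± 0.24, 3.98-fold). Sarcomere genes had 25 lower and 7 higher regions, at 15 of 34 genes for the lower ones (adjusted p = 0.76). They included LDB3 (chr10:88428102–88428600, an intron, 2.90 ± 0.18 to 0.347 ± 0.28), NEBL (chr10:21181402–21181700, an intron, 1.60 ± 0.52 to 0.147 ± 0.0028), ACTC1 (chr15:35105302–35105500, a transcription end site, 2.20 ± 1.4 to 0.367 ± 0.096) and TNNT2 (chr1:201342202–201342300, an exon, 1.44 ± 0.47 to 0.624 ± 0.037).

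Cardiac mesoderm genes had 18 lower and 6 higher regions, 9 of 17 genes at a lower one (adjusted p = 0.747), with GATA4 at 3 lower regions led by chr8:11588402–11588500 (2.99 ± 0.24 to 0.917 ± 0.48, 3.26-fold), and ALDH1A2 at 2. PDGFRA, the other sort marker, had a higher exon region (chr4:55143402–55143600, 0.458 ± 0.20 to 2.95 ± 0.12, 6.45-fold) and a lower one (chr4:55133502–55133600, 3.70 ± 0.16 to 1.58 ± 0.63, 2.34-fold). KDR was lower upstream of the gene (1.44 ± 0.22 and 0.413 ± 0.078). Cardiac transcription factors were at higher regions for 8 of 20 genes (adjusted p = 0.332) and at 28 lower regions, with MYOCD (chr17:12567902–12568100, intergenic, 3.04 ± 0.38 to 0.883 ± 0.49), the coactivator of serum response factor, among the lower. The BMP, NODAL and TGF-beta list had 24 lower and 4 higher regions (adjusted p for direction = 0.658). Neural genes had 5 higher and 1 lower (adjusted p = 0.494), such as POU3F2 (0.676 ± 0.064 to 3.79 ± 0.042) and RBFOX3 (0.646 ± 0.62 to 3.27 ± 0.95), and clustered protocadherins 5 higher and 2 lower (adjusted p = 0.585), such as PCDHGC5 (0.458 ± 0.20 to 3.14 ± 0.055). Pluripotency genes had 7 higher and 6 lower regions, with 3 higher at L1TD1, led by chr1:62662202–62662500 (0.331 ± 0.13 to 3.55 ± 1.7), and a lower 3' UTR region at NANOG (chr12:7948102–7948200, 4.75 ± 0.35 to 2.68 ± 0.20, 1.77-fold). Primitive streak genes had 3 higher and 9 lower regions (adjusted p = 1), 6 of them at ROR2, and EOMES, a T-box factor of the streak, had 1.10 ± 0.15 and 0.132 ± 0.018 in an intergenic region.

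BCOR, a Polycomb corepressor on chromosome X, led the higher list with 7 regions, before ESRRG with 5 and LOC100506641, LOC100507540 and TBX1 with 4. CUX1 with 8 lower regions and AGAP1 and GALNT2 with 7 followed PRDM16 and SMAD7. Values were 0.661 ± 0.25 and 2.95 ± 0.90 at TBX1, a factor of the outflow tract, and 3.95 ± 0.29 and 0.648 ± 0.098 at CUX1. Intergenic sequence held 40.6% of higher and 28.6% of lower regions (adjusted p = 3.0e-38, Fisher's exact test, two-sided), introns 45.8% against 53.6% (adjusted p = 2.5e-15) and exons 3.27% against 5.80% (adjusted p = 1.4e-09). CpG islands held 188 and 120 (adjusted p = 1.4e-10). Alu elements were 43.9% of higher and 7.54% of lower regions, an odds ratio of 9.61, in the same direction on 23 of 23 chromosomes (adjusted p = 2.3e-05, permutation over chromosomes). Median signal was 0.556 ± 0.11 and 3.14 ± 0.055 in the higher list and 2.51 ± 0.019 and 0.702 ± 0.023 in the lower list.

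From hESC to cardiomyocytes the comparison spans the whole differentiation. Higher regions were frequent at cardiac transcription factor genes, 12 of 20 against 19.2% of the other genes (adjusted p = 0.0089, Fisher's exact test, two-sided). TBX3 was higher in an exon at chr12:115109702–115110100 (0.148 ± 0.21 to 3.65 ± 0.25), TBX2 in its 3' UTR at chr17:59482702–59483300 (0.136 ± 0.19 to 3.46 ± 1.0) and GATA6 in an intron at chr18:19758202–19758300 (0.727 ± 0.64 to 3.82 ± 0.33, 5.25-fold). HOX genes, which set position along the body axis, had 11 higher and 1 lower region, and the HOXB3 exon at chr17:46637202–46637300 had 0.136 ± 0.19 to 2.07 ± 1.6. POU5F1 was higher in an exon at chr6:31138202–31138300 (0.545 ± 0.77 to 3.22 ± 1.2, 5.91-fold). Regions of MYH6, by contrast, were lower, led by an exon at chr14:23869902–23870100 (4.95 ± 0.52 to 1.34 ± 0.47, 3.69-fold).

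The 12 cardiac transcription factor genes were PRDM16, IRX2, CASZ1, IRX3, GATA6, IRX4, NFATC1, TBX2, TBX3, ZFPM2, IRX1 and IRX5, of which those after IRX3 were named after their values were seen. Their regions included IRX2 (chr5:2763002–2763100, intergenic, 0.864 ± 0.45 to 3.91 ± 0.21), IRX3 (chr16:54325502–54325800, intergenic, 0.739 ± 1.0 to 3.21 ± 0.86) and CASZ1 (chr1:10712002–10712200, a transcription end site, 0.431 ± 0.23 to 2.94 ± 0.95). Over its alternatives the adjusted p of this excess ran from 4.7e-04 near start sites to 0.0504 with 10000 matched random lists, which is not past the threshold, and it was 0.0151 with 100000. Counted by region, the list had 22 higher and 15 lower (adjusted p for direction = 0.751). PRDM16 had 2 higher and 8 lower regions, the latter led by chr1:3087302–3088000 (4.24 ± 0.56 to 0.717 ± 1.0, 5.91-fold), and 8 of the 20 genes were at lower regions (adjusted p = 0.71), GATA4 among them (chr8:11600102–11600400, 3.82 ± 0.38 to 0.698 ± 0.65, 5.47-fold). HOX genes were at higher regions for 5 of 10 (adjusted p = 0.548), with HOXB3 at 5, HOXB-AS3 at 4 and HOXB1 at 2, and their direction had an adjusted p of 0.263 with regions and of 0.944 with genes as units. HOXB1 spanned chr17:46607702–46608400 (0.284 ± 0.017 to 3.02 ± 0.22), and HOXA3 was listed at 0 in hESC and at 1.79 ± 1.4 in cardiomyocytes.

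**Figure D3:**
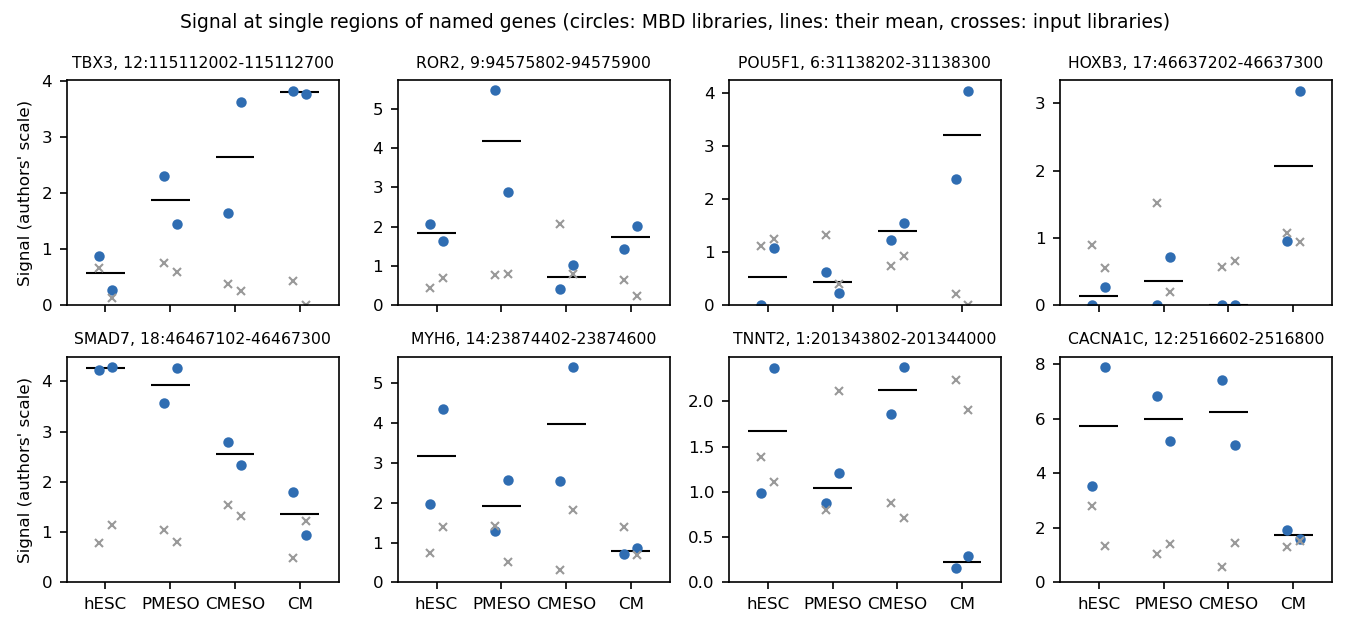
MBD signal (y axis, the authors' normalised read density) at 1 region of each of 8 genes in the 4 stages (x axis), with circles for MBD libraries, lines for their means and crosses for input libraries. The TBX3 and POU5F1 regions were highest in cardiomyocytes, and the MYH6, TNNT2, SMAD7 and CACNA1C regions were lowest there.

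Pluripotency genes had 10 higher and 7 lower regions, with 9 of 22 genes at a higher one (adjusted p = 0.548). LEFTY1, a NODAL antagonist, had 2 higher regions, led by an exon at chr1:226075202–226075300 (0.727 ± 0.64 to 3.38 ± 0.28, 4.65-fold), and LIN28B had a higher region (1.76 ± 0.40 to 5.63 ± 0.021, 3.20-fold) and a lower one (2.24 ± 1.1 to 0.119 ± 0.17). Cardiac mesoderm genes were at higher regions for 7 of 17 (adjusted p = 0.564), among them FOXF1 (chr16:86550402–86550600, intergenic, 0.295 ± 0.42 to 2.50 ± 1.2). Endothelial and blood genes had 9 higher and 2 lower regions (adjusted p for direction = 0.585), such as SOX7 (0.444 ± 0.63 to 3.29 ± 0.26) and CD34 (2.27 ± 0.13 to 6.46 ± 0.69), and the GATA2 promoter at chr3:128212402–128212700 was listed at 0 in hESC and at 2.45 ± 0.59 in cardiomyocytes. Smooth muscle and fibroblast genes had 5 higher and 4 lower (adjusted p = 1). Sarcomere genes were at lower regions for 13 of 34 (adjusted p = 0.511), among them ACTN2 (chr1:236853202–236853400, an intron, 3.81 ± 0.58 to 0.553 ± 0.44) and TTN (chr2:179494302–179494500, an intron, 3.73 ± 1.1 to 0.431 ± 0.40), and at higher regions for 5, of which ACTA1, skeletal actin, was listed at 0 in hESC and at 1.99 ± 0.45 in cardiomyocytes. CACNA1C had 6 lower regions (5.72 ± 3.1 and 1.75 ± 0.23 at chr12:2516602–2516800), within 14 lower and 9 higher regions of calcium and ion channel genes (adjusted p for direction = 1). BMP, NODAL and TGF-beta genes were at lower regions for 10 of 24 (adjusted p = 0.511), with SMAD7 at 5, led by chr18:46467202–46467300 (4.54 ± 0.26 to 0.742 ± 0.64, 6.13-fold). Zinc finger genes were at lower regions for 17 of 150 against 20.8% of the others (unadjusted p = 0.0031, adjusted p = 0.156). DNA methylation genes had 3 higher and 6 lower regions (adjusted p = 1), including MBD1 (0.136 ± 0.19 to 2.73 ± 0.19), GADD45G (0.420 ± 0.18 to 2.61 ± 2.1) and DNMT3A (3.81 ± 0.78 to 0.861 ± 0.81), and imprinted genes 9 higher and 3 lower (adjusted p = 0.658), including DIRAS3 (0.136 ± 0.19 to 3.12 ± 0.32) and DLK1 (1.01 ± 0.46 to 2.60 ± 0.20).

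HOXB3, LOC284801 and NOL4L led the higher list with 5 regions each, before BCOR and the forkhead gene FOXP4 with 4, and PRDM16 led the lower list before CACNA1C, CUX1, GALNT2 and PEMT with 6. Their regions included NOL4L (chr20:31058002–31058100, an intron, 0.852 ± 0.049 to 3.91 ± 0.21), FOXP4 (chr6:41520402–41520500, an intron, 0.136 ± 0.19 to 2.71 ± 0.56), CUX1 (chr7:101596702–101597100, an intron, 4.63 ± 1.5 to 0.767 ± 0.27) and PEMT (chr17:17480202–17480400, an exon, 3.79 ± 1.2 to 0.396 ± 0.054). Higher regions numbered 5850 and lower ones 3870 (60.2%, 59.2% to 61.2%), and without Alu regions the higher share was 49.3%. CpG islands held 300 higher and 14 lower regions (adjusted p = 5.1e-49, Fisher's exact test, two-sided). Introns held 42.3% of higher and 55.5% of lower regions (adjusted p = 2.3e-36), intergenic sequence 41.6% against 28.6% (adjusted p = 3.1e-38) and promoters 5.95% against 4.50% (adjusted p = 0.0046). Alu elements were 38.0% of higher and 3.49% of lower regions, an odds ratio of 17.0, in the same direction on 23 of 23 chromosomes (adjusted p = 2.3e-05, permutation over chromosomes). Median signal was 0.42 ± 0.18 and 3.00 ± 0.15 in the higher list and 2.98 ± 0.029 and 0.264 ± 0.035 in the lower list. The cardiomyocyte input median was 0.675 at the higher and 0.953 at the lower regions.

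Overlapping regions of several comparisons were joined into courses over all stages. The lists behind a course share libraries, which alone gives some regions of each course. Of 41719 merged regions 4572 were called in at least 2 comparisons, and 3829 of these fitted several courses because calls were missing. The best-defined course was lower in cardiomyocytes than in each earlier stage, with 346 regions, against 130 and 70 simulated without differences between stages (1000000 and 10000000 windows). PRDM16 had 3 of them, at chr1:3087302–3088000, chr1:3115402–3115700 and chr1:3208802–3209200. SMAD7 had 2, at chr18:46461102–46461900 and chr18:46473502–46473800, and LDB3 (chr10:88428102–88428700), CACNA1C (chr12:2516602–2516900), MEF2A (chr15:99995302–99995500) and TCF7L2 (chr10:114760802–114761000), a WNT effector, had 1 each. Higher in cardiomyocytes than in every earlier stage were 139 regions (121 and 87 simulated), among them L1TD1 (chr1:62662102–62662500), ZSCAN10 (chr16:3151802–3152200), the epithelial splicing regulator ESRP2 (chr16:68270202–68270700) and IRX2 (chr5:2754802–2755500). In 49 regions (64 and 57 simulated) the signal was higher in PMESO, CMESO and cardiomyocytes than in hESC, among them H19 (chr11:2019602–2019700), TBX3 (chr12:115111902–115112700), WNT5A (chr3:55508202–55508700) and TMEM88 with KDM6B (chr17:7756202–7757600). Lower in CMESO alone were 125 regions (211 and 129 simulated), 92 of them at Alu elements, among them DNMT3A (chr2:25569102–25569200) and EPHA7 (chr6:94275602–94275700). Lower in PMESO alone and lower from PMESO on were 14 regions each, higher in CMESO alone 4 and higher in PMESO alone 2, each below both simulated values. Only the 2 courses that set cardiomyocytes apart exceeded both. Simulated calls were single windows. Single windows made up 71.1% to 81.5% of the lists with cardiomyocytes and 84.2% to 91.5% of the other lists. Whether region width adds to the excess of these courses was not tested. Genes in this paragraph outside the fixed lists were chosen after their values were seen.

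Comparisons that share no library had few regions in common. Regions lower or higher from hESC to PMESO met those of CMESO to cardiomyocytes in 11 cases, 7 in the same direction. For hESC to CMESO with PMESO to cardiomyocytes there were 15 shared regions, 8 in the same direction, and for hESC to cardiomyocytes with PMESO to CMESO 10, with 3 in the same direction. No association of direction between the comparisons was detected (adjusted p = 0.90, 0.90 and 1, Fisher's exact test, two-sided). With 10 to 15 shared regions per test, only a strong association could be detected. Each pair of these lists shared fewer regions than independent lists would with 1000000 windows, and most shared more than with 10000000. Whether the overlap is smaller or larger than that of independent lists is therefore not settled. Lists with a shared stage on the same side of both overlapped more, with 883 regions lower in cardiomyocytes than both PMESO and hESC, and 736 lower than both CMESO and PMESO. Shared libraries alone gave 628 and 556 in a simulation of 1000000 windows without differences between stages, and 423 and 371 with 10000000. Of 24 list pairs with the shared stage on the same side of both, 3 lay above both simulated values, all among regions lower in cardiomyocytes. Region width was not simulated and may add to these 3. Another 19 lay below both and 2 between. All 12 pairs without a shared library lay below both as well, so the simulated values were too high as a reference, and an overlap below them decides nothing. The overlap of regions lower in CMESO than PMESO with those higher in cardiomyocytes than CMESO, 596, lay between the simulated 874 and 572.

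A list was not selected on the 2 stages it does not compare, and limma contrasted these, with a variance taken from all 8 MBD libraries. It called 14 of 47059 regions at an adjusted p below 0.05, while 3547 (7.54%) had an unadjusted p below 0.05. That variance includes the stages used for selection. With only the 4 libraries of the contrasted stages there were 22 calls and 6.59% with an unadjusted p below 0.05, and leaving out 1 library gave 5 to 149 calls. Of the 14 calls 4 were among regions higher in cardiomyocytes than CMESO, with more signal in PMESO than in hESC. On simulated 4-fold changes at 200 regions per list with a mean signal of at least 1, limma recovered 42.5% to 68.0% in lists with 99 bp windows. In lists with wider windows it recovered 84.0% to 98.0%. There the simulation drew each 99 bp of a window as separate fragments, which may overstate recovery. The simulation had no difference in the stages used for selection, so recovery in the real fit may be lower. In the lists of regions higher in cardiomyocytes than hESC the median signal was 1.46 in PMESO and 1.33 in CMESO, between those of the compared stages.

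Of 20 core genes of pluripotency, mesoderm and heart, 16 had at least 1 region, and TBXT, MESP1, NKX2-5 and ISL1 had none. ROR2 had 19, TTN 8, and MYH6 and GATA4 7 each over the 12 lists. Over all 21 gene lists, 3 of 252 tests of gene counts passed the threshold and 17 had an unadjusted p below 0.05. For direction within lists, Fisher's exact test passed the threshold in 0 of 126 tests, and 8 had an unadjusted p below 0.05.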

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

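The alternatives that leave out Alu regions, keep regions above the median signal difference, use 100000 random gene lists, change the pseudocount, set a minimum on mean signal, leave out replicates or fit 4 libraries were chosen after seeing the data, as were all those of repeat classes. Over 131 results and 574 alternative values, 446 kept direction and side of the threshold or moved little, 83 moved, 29 lost the threshold, 12 gained it and 4 reversed. The cause was not tested except where the construction of an alternative gives it. The higher share of regions by covered length was 61.7% from hESC to PMESO, 66.9% from CMESO, 41.0% from PMESO and 61.5% from hESC to cardiomyocytes. Above the median signal difference it was 50.2% from hESC to PMESO and 54.1% from hESC to cardiomyocytes. Without Alu regions it was 57.0% from hESC to PMESO, 45.9% from PMESO to CMESO, 39.8% from hESC to CMESO and 31.3% from PMESO to cardiomyocytes, and it reversed to 41.3% from CMESO and to 49.3% from hESC to cardiomyocytes. Leaving out a replicate dropped regions whose remaining libraries overlapped, and moved these shares by less than 0.2 points, as the lists had been selected for such separation. The exon difference from CMESO to cardiomyocytes reversed to 0.348 points without Alu regions, and the class of other repeats from hESC to CMESO reversed to −0.154 points above the median difference. Among annotation classes 145 of 168 alternative values kept the call. Shared regions of comparisons without a common library numbered 7, 2 and 3 with overlap of 50% of both regions, 73, 86 and 59 within 1000 bp, and 1, 3 and 3 above the median difference, by construction of these rules. Regions called by limma in the stages not compared numbered 9 with a pseudocount of 0.1, 23 with a mean signal of at least 1, 19 with a replicate block and 22 with only the 4 libraries of these stages. Leaving out a replicate gave 5 to 149, with 149 without CMESO replicate 2 and 5 without cardiomyocyte replicate 1, and the lone library of the stage was then assumed to vary like the others. Of the 3 gene list calls 1 was past the threshold without intergenic regions and 0 with 10000 random lists, each with an adjusted p of 0.0504. The smallest p that 10000 random lists can give is 2e-04, so over 252 tests a single list alone could not pass with them. For cardiac transcription factors from CMESO to cardiomyocytes the adjusted p was 0.567 near start sites, 0.545 without intergenic regions, 0.0504 with 10000 and 0.0353 with 100000 random lists. From hESC to cardiomyocytes that list ran from 4.7e-04 near start sites to 0.0504 with 10000 random lists, with 0.0151 for 100000. For sarcomere genes it was 0.213 without intergenic regions, 0.0504 with 10000 random lists, 0.0202 with 100000 and 0.0161 near start sites. In the tests of direction, 1 list passed near start sites (cardiac transcription factors from hESC to cardiomyocytes, adjusted p = 0.0278). Not run were the split by the authors' scores, which were all 0, and the count models, since there were no counts. The depth of CMESO replicate 1 limits what can be seen at regions near 0 in CMESO.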

Other observations

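In the part on Alu elements the test of the input, in the part on sarcomere genes the test at like MBD signal, and in the part on the cardiomyocyte input the tests against cardiomyocyte and hESC MBD signal, were chosen after the result was seen, as was the matching on signal. At regions of lists that did not involve cardiomyocytes, which are free of selection on them, Alu regions minus other regions differed from the other unselected stage by 0.20 (log2 scale, 95% interval over chromosomes 0.18 to 0.23) in cardiomyocytes. In hESC the mean was −0.020 and in PMESO 0.023, over lists that went both ways. Matched on signal, lists ran from −0.22 to 0.22 in hESC, −0.19 to 0.16 in PMESO, −0.28 to −0.15 in CMESO and 0.13 to 0.28 in cardiomyocytes. Each list enters the values of both its unselected stages with opposite sign, so the values of the stages are not independent. Here and below, intervals over chromosomes measure spread between chromosomes of the same libraries, not between cultures.

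Alu elements were frequent among regions lower in CMESO than in hESC, PMESO or cardiomyocytes. The shallow CMESO replicate 1 alone is argued against, since replicate 2 by itself gave −0.17 (log2, −0.20 to −0.15, 26790 regions of lists without CMESO). A loss of Alu fragments in library preparation or mapping that also acts on the input is argued against by 0.0050 (log2, −0.022 to 0.030, 20906 regions) in the input against hESC or PMESO. With the lists set against the cardiomyocyte input, itself low at Alu regions, included, it was 0.042. Weaker capture of all CpG-dense DNA in CMESO stays open. Over lists without CMESO, CpG islands stood at 0.16 (0.10 to 0.21) while Alu regions stood at −0.20. Those islands came mostly from lists higher in the later stage, so this value alone decides little. Called islands went both ways in CMESO, with 3 higher and 22 lower against PMESO, and 43 higher and 2 lower against hESC. In cardiomyocytes 81 were higher and 14 lower than in CMESO. A batch of MBD capture that differs between stages stays open, since the labels give none, and lower Alu methylation in cardiac mesoderm may be biological, as a hypothesis found on the same data.

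Sarcomere genes were frequent among regions lower in cardiomyocytes than in CMESO. Copy number or DNA recovery would lower the input, which differed by 0.14 (log2, −0.02 to 0.41, 19 regions) where the MBD signal differed by −1.60. The cardiomyocyte input mostly rises as MBD signal falls, so this value alone decides little. Set against 3578 other regions of the same list at like cardiomyocyte MBD signal, the input ratio was higher by 0.38 (log2, 0.14 to 0.62), which argues against a loss at sarcomere genes in particular. Genes that carry many regions anyway stay open. The 10000 random lists were matched only on number of regions from hESC to PMESO. They gave a permutation p of 2e-04, the smallest they can give, and an adjusted p of 0.0504, not past the threshold. Matching on that comparison alone may not capture how many regions a gene tends to carry, so this test does not decide. A candidate explanation is loss of methylation at contractile genes as they become active in cardiomyocytes, a hypothesis that these data on methylation alone leave untested. The call was not past the threshold without intergenic regions (adjusted p = 0.213).

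Cardiomyocyte input signal was mostly low where cardiomyocyte MBD signal was high. In 10 bins of rising MBD signal at hESC to PMESO regions, its mean fell from 1.10 to 0.396 over the first 9 and was 3.24 in the last, where the CMESO input was also high (2.50). Selection of regions on cardiomyocyte libraries is argued against by lists without cardiomyocytes, where the Spearman correlation across regions was −0.54 (−0.56 to −0.52, 14917 regions, which are not independent replicates). Lower depth of the input is argued against by hESC input replicate 1, of similar depth, with 0.11 (0.09 to 0.13, 27802 regions). Loss of CpG-dense sequence whatever its methylation stays open. Within Alu regions the third with most MBD signal differed from the third with least by −0.63 (log2, −0.67 to −0.62, 4640 regions) in the input, but CpG density was not held fixed. Another candidate source is an input depleted of methylated fragments, as an unbound fraction would be, and its effect on the calls is unknown because the caller's use of the input was not given; no biological explanation was tested.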
